A study of Homo sapiens with 18 samples.

How the data were processed

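RNA was measured by poly(A) sequencing (TruSeq RNA v2, RNA from RNeasy Mini, per the labels' protocols) in 18 libraries, 3 for each of 6 groups: BxPC3, Panc327 and SUIT2 cells treated for 6 h with DMSO or with 100 nM THZ1. The deposited files hold raw counts of reads per gene symbol, 1 file per library, made by the authors with bcl2fastq 1.8.4, TopHat2 2.1.0 and HTSeq 0.6.1 on hg38, per the submitters' processing notes. The annotation, the strand setting and the counting mode are not given in the sources used here. Each file has 26485 symbols and 5 summary entries of the counting tool, which held 21.3% to 64.6% of all records and were left out of library sizes and tests. The files hold 0 mitochondrially encoded genes, so a planned scaling to those genes was not run.

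Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14011. Libraries were scaled by TMM, a model with 6 group means (12 residual degrees of freedom) was fitted with the robust edgeR quasi-likelihood method, and Benjamini-Hochberg adjusted p under 0.05 made a call. THZ1 was compared with DMSO in each line, responses were compared between lines by the difference of these contrasts, and lines were compared with DMSO. Fold changes are log2 with SE, and levels are TMM-scaled CPM with SD. The SE is approximate: the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Composition scaling centres the median gene at 0, so directions are relative to the median gene, and a change of total RNA per cell is not measured.

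Gene lists were written before the data were examined, as were the groups, tests, alternatives and the rule for naming genes. Of 35 lists 34 had tested members. Each was tested with limma camera (preset correlation 0.01), with a correlation estimated from the data and with fry, adjusted over the lists of a contrast. Which lists are described was chosen after their values were seen. The text names the 6 genes with the largest rise and fall per THZ1 contrast, 5 per direction for differences of responses and 3 per direction for DMSO, among called genes with a mean of at least 10 CPM in a group compared, and for THZ1 and DMSO contrasts with all 3 libraries of a group on 1 side of the other 3. It also names 15 genes fixed beforehand, GATA6, KRT17 and VIM with DMSO, and up to 3 members per direction of each list described. Genes from these sets whose calls rest on single libraries are partly left out, and 2 other genes that meet the rule are not reported here. Where a group had 0 counts, folds are lower bounds against a floor of 3 counts over the group, and with 1 to 3 counts ratios have a 95% interval. Gene positions are from GENCODE 29 on GRCh38, to which 23862 symbols were matched by name and 46 by an older symbol.

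The alternatives tried were RLE size factors, library size only, no filter, DESeq2, limma voom, only the lines compared, a replicate block, a 2-fold threshold and leaving out each library in turn. Agreement was also computed for genes with a mean of at least 10 CPM. The pipeline was tested on simulated data in which 200 of 14011 genes were changed. The simulated dispersion was 0.01, where the common dispersion of the data was 0.0012, so the shares recovered are not those of these data. In BxPC3 and Panc327, 69.4% and 73.4% of genes were called with THZ1. The simulation therefore does not test the scaling or the number of false calls where most genes change. For a THZ1 contrast it called 59.7%, 94% and 97% of genes changed by 1.5-fold, 2-fold and 4-fold, with 7 false calls. For a difference of responses it called 20.9%, 71.6% and 90.9%, with 9 false calls, and for a DMSO contrast 56.7%, 92.5% and 100%, with 10. Camera called the 1 list that was raised and 0 others. For splits of the libraries, all 10 were run within a line, and 60 were drawn for differences of responses, a number set for running time after a first run with 100 draws.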

Results

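Poly(A) RNA was sequenced from 3 human pancreatic ductal adenocarcinoma lines, BxPC3, Panc327 and SUIT2, after 6 h with 100 nM THZ1 or with DMSO, the vehicle control. THZ1 is a covalent inhibitor of CDK7, the kinase of the general transcription factor TFIIH that phosphorylates RNA polymerase II, and it also binds CDK12 and CDK13. The series title concerns SIRT6, a chromatin deacylase, and its part in the integrated stress response and in resistance to transcriptional inhibition. The comparisons ask what THZ1 changed in each line, where the lines differed in their response, and how they differed before treatment. Each of the 6 groups held 3 libraries, and the labels do not say that these came from separate cultures, so p-values measure only the spread between these samples. Gene counts per library ranged from 5626146 to 8631273. Means were 8037100 ± 363237 with DMSO and 7078400 ± 313778 with THZ1 in BxPC3 (SD, n = 3). They were 8483820 ± 141566 and 6054640 ± 585213 in Panc327, and 7642330 ± 476480 and 7566450 ± 780122 in SUIT2 (SD, n = 3). Of 26485 genes, 14011 had enough counts to be tested. Expression levels are in CPM after TMM scaling, and coordinates are from GENCODE 29 on GRCh38.

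Libraries separated by line on the leading components of a principal component analysis, which held 50.3% and 37.0% of the variance, and by treatment on the third, which held 8.41%. THZ1 changed what the reads aligned to in BxPC3 and Panc327. Records that aligned to several places made up 22.8% ± 0.805 of each BxPC3 count file with THZ1 and 12.8% ± 0.609 with DMSO (SD, n = 3). In Panc327 the shares were 52.8% ± 1.81 and 13.6% ± 0.149, and in SUIT2 12.9% ± 0.902 and 13.2% ± 0.726 (SD, n = 3). The 3 THZ1 values lay above the 3 DMSO values in BxPC3 and in Panc327, each with an exact 2-sided permutation p of 0.1, the smallest that 3 against 3 allows. The p was 0.7 in SUIT2. These shares count alignments, so a read that aligned to several places may stand for more than 1 record.

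**Figure D1:**
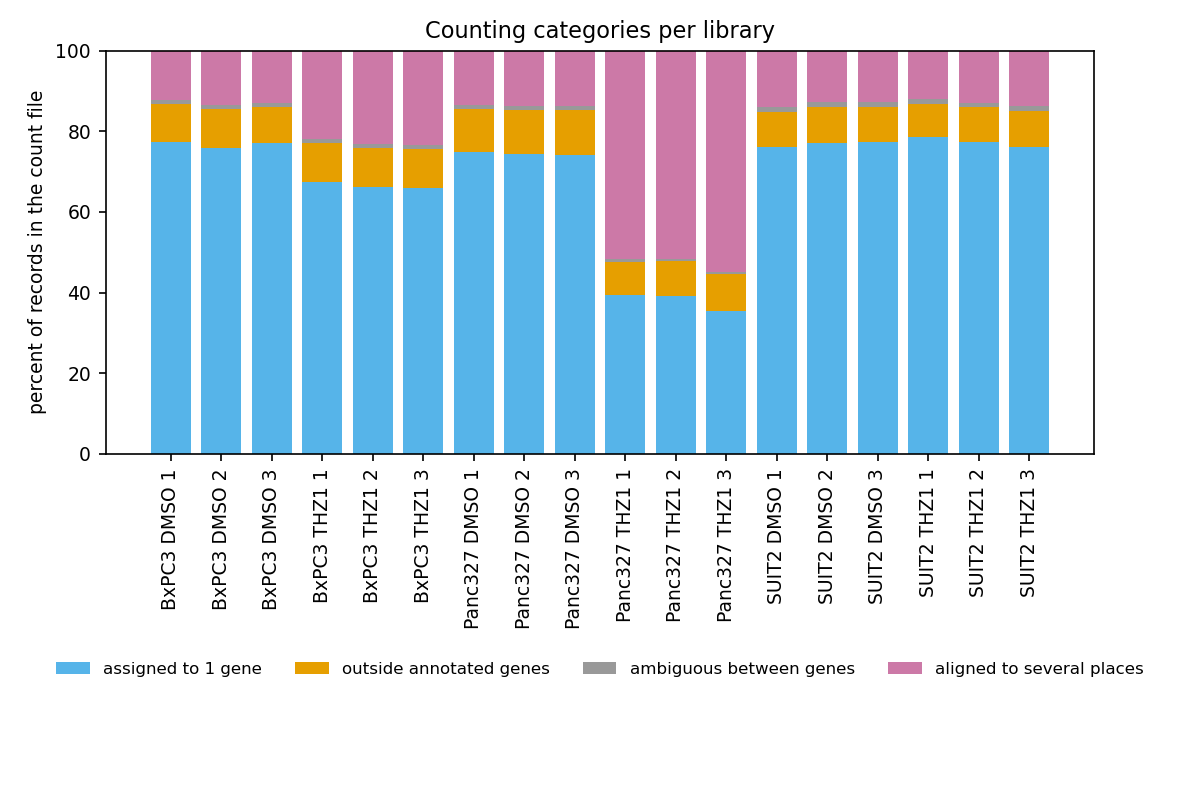
Share of each library's count file in 4 counting categories, in percent of records, one stacked bar per library. Records aligned to several places averaged 22.8% with THZ1 in BxPC3 and 52.8% in Panc327, against 12.8% and 13.6% with DMSO.

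In BxPC3, THZ1 raised the immediate early transcription factor FOS from 11.4 ± 0.564 to 146 ± 5.61 CPM (SD, n = 3; log2 fold change 3.68, SE 0.08, edgeR quasi-likelihood adjusted p = 2.73e-58). ARC, another immediate early gene, rose from 0.270 ± 0.171 to 10.5 ± 0.331 CPM (log2 fold change 5.19). POLR2A, the catalytic subunit of RNA polymerase II, rose from 432 ± 24.1 to 1388 ± 13.2 CPM, and HEXIM1, an inhibitor of the elongation kinase P-TEFb, from 98.2 ± 10.2 to 184 ± 7.65 CPM (SD, n = 3). CYP1B1, a cytochrome P450 of oestrogen and xenobiotic metabolism, fell from 117 ± 6.42 to 6.58 ± 1.08 CPM, and the zinc finger gene ZC3H4 from 74.9 ± 5.41 to 6.56 ± 1.43 CPM.

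FOS lies on chromosome 14 from 75278774 to 75282230, POLR2A on chromosome 17 from 7484366 to 7514616, and HEXIM1, a gene of 1 exon, on chromosome 17 from 45148502 to 45152101. CYP1B1 lies on chromosome 2 from 38066973 to 38109902 and ZC3H4 on chromosome 19 from 47064187 to 47113752. Other large rises were those of RNA45S5, the precursor of ribosomal RNA (8.51), LINC00926 (4.58), LSMEM1 (3.54) and the pseudogene SLC7A5P2 (3.45), as log2 fold changes. Other large falls were those of RPSAP52 (-4.79), USH1G (-3.81), BDKRB2, the bradykinin B2 receptor (-3.52), and C16orf54 (-3.38). Reads of RNA45S5, SLC7A5P2 and RPSAP52, which have near-identical copies, and of LSMEM1 and RPSAP52, which overlap IFRD1 and HMGA2, could not be assigned with certainty, since the counting does not state strand.

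Genes of abundant housekeeping machinery rose together in BxPC3. Fold changes also rose with expression level over protein-coding genes with a mean of at least 10 CPM (Spearman correlation 0.398). Lists were not matched for expression in the camera test. Whether these lists, or the zinc finger list described below, go beyond that trend was not tested. All 78 cytoplasmic ribosomal protein genes rose (78 adjusted over the list alone), with a median log2 fold change of 0.89, among them RPL39 (1.16) and RPLP2 (1.14). The list stood above other genes by camera with adjusted p = 3.44e-36, but adjusted p = 0.085 with an estimated correlation. Of 56 nuclear genes of respiratory chain subunits, 55 rose and 0 fell (the same counts adjusted over the list alone), with a median of 0.88, led by COX6C and NDUFA4 (1.2 each). This list kept its call (adjusted p = 0.0206 with an estimated correlation). Of 24 glycolysis genes 18 rose and 2 fell (18 and 3 adjusted over the list alone), among them GAPDH (1.11) and PGK1 (0.95), with adjusted p = 6.5e-06 by camera and adjusted p = 0.0973 with an estimated correlation. Of 15 common reference genes 13 rose and 2 fell over all genes and over the list alone, with B2M at 1.07. Their camera adjusted p was 5.27e-06, and adjusted p = 0.085 with an estimated correlation. With libraries scaled by size alone, the medians in BxPC3 were 0.49 for ribosomal protein genes, 0.48 for respiratory chain genes, 0.38 for glycolysis genes (13 higher, 6 lower) and 0.35 for reference genes (10 higher, 4 lower), in place of 0.89, 0.88, 0.77 and 0.74.

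Genes of chaperones moved in both directions in BxPC3. Of 23 targets of the unfolded protein response in the endoplasmic reticulum, 17 rose and 4 fell (17 and 4 adjusted over the list alone). The co-chaperone DNAJC3 (1.09) and the disulphide isomerase PDIA6 (0.92) rose, while the transcription factor XBP1 fell (-1.70). The camera adjusted p was 0.000544, and adjusted p = 0.108 with an estimated correlation. The median of 0.42 came to 0.03, with 11 higher and 7 lower, when libraries were scaled by size alone. Of 19 heat shock genes 12 rose and 4 fell (12 and 4 adjusted over the list alone), with HSPA1B at 1.62, DNAJB1 at -1.35 and HSPA8 at -0.71. Reads of HSPA1B are uncertain, because HSPA1A is nearly identical. The camera adjusted p was 0.0328, and adjusted p = 0.28 with an estimated correlation. The heat shock median of 0.37 turned to -0.03, with 9 higher and 8 lower, when libraries were scaled by size alone. Of 12 RNA polymerase II subunit genes 9 rose and 2 fell (9 and 2 adjusted over the list alone), with POLR2A at 1.68 and POLR2F at 1.2 (camera adjusted p = 0.00618, adjusted p = 0.0924 with an estimated correlation), and the median of 0.76 came to 0.37 with scaling by library size alone.

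Of 408 numbered zinc finger (ZNF) genes, many of which have short-lived transcripts, 269 fell and 43 rose (271 and 43 adjusted over the list alone), with a median of -1.03. ZNF839 (-3.07), ZNF324 (-2.75) and ZNF526 (-2.71) fell, and ZNF512 rose (1.57). This list was lower than other genes by camera (adjusted p = 7.62e-08) and kept its call (adjusted p = 0.00274 with an estimated correlation). Of 35 genes of homologous recombination and the Fanconi anaemia pathway 24 fell and 5 rose (24 and 5 adjusted over the list alone), with FANCF at -2.83, XRCC2 at -2.09 and BLM at -1.85. The camera adjusted p was 0.000743, and adjusted p = 0.0924 with an estimated correlation. Of 35 immediate early genes 20 rose and 11 fell (20 and 11 adjusted over the list alone). FOS (3.68), IER2 (2.83) and JUNB (2.59) rose, while FOSL1 fell (-1.15). The list passed neither version of the test (camera adjusted p = 0.137, adjusted p = 0.484 with an estimated correlation). Scaled by library size alone, 16 immediate early genes were higher and 15 lower in BxPC3 (median 0.16 in place of 0.55), and the repair median of -0.52 came to -0.91.

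The integrated stress response genes of BxPC3 went both ways. Of 37 members, 16 rose and 10 fell (16 and 10 adjusted over the list alone), and the median of 0.07 did not stand apart from other genes (limma camera adjusted p = 0.536). It turned to -0.25 when libraries were scaled by size alone. ATF4, the transcription factor at the centre of the response, went from 228 ± 6.31 to 300 ± 8.47 CPM (SD, n = 3; log2 fold change 0.39, SE 0.04, edgeR adjusted p = 9.97e-14). Its target ASNS, asparagine synthetase, rose (0.98), as did the transcription factor ATF3 (1.40) and the one-carbon enzyme SHMT2 (0.92). DDIT3, which encodes the pro-apoptotic factor CHOP, fell from 8.41 ± 0.458 to 1.55 ± 0.583 CPM, a log2 fold change of -2.42 (SE 0.24). TRIB3 (-1.04), PPP1R15A (-1.12), CEBPB (-1.08) and CHAC1 (-1.22) also fell. SESN2 passed the test at 0.30 (edgeR adjusted p = 0.0175), but not without DMSO replicate 1 (0.24) or without THZ1 replicate 2 (0.23). With libraries scaled by size alone, SESN2 came to -0.10 and ATF4 to 0.00, and neither passed the test.

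Among the genes tied to the drug and to the series title, CDK7 fell in BxPC3 from 30.9 ± 1.25 to 20.3 ± 0.725 CPM and CDK12 from 100.0 ± 2.53 to 67.1 ± 3.22 CPM (SD, n = 3). CDK13 passed the test at a log2 fold change of 0.22, which turned to -0.18 when libraries were scaled by size alone. SIRT6, on chromosome 19 from 4174109 to 4182604, went from 13.8 ± 0.989 to 21.7 ± 1.01 CPM (log2 fold change 0.65, SE 0.12, edgeR adjusted p = 1.42e-06), and to 0.25 (adjusted p = 0.0547) when libraries were scaled by size alone. MYC fell by 0.53 and the anti-apoptotic gene MCL1 by 0.40 on the log2 scale. THZ1 changed 9722 of 14011 genes in BxPC3, 4938 of them higher and 4784 lower, and 803 and 2109 of these at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Scaling by library size alone took the median of all genes from 0.00 to -0.35, and 26.8% of the calls were then higher in place of 50.8%.

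In Panc327, MYC fell from 302 ± 10.1 to 71.3 ± 8.27 CPM with THZ1 (SD, n = 3; log2 fold change -2.09, SE 0.06, edgeR adjusted p = 4.51e-49). POLR2A rose from 669 ± 10.4 to 1152 ± 20.2 CPM. ZC3H4 fell from 95.8 ± 0.918 to 3.79 ± 0.627 CPM, and HOMEZ, a homeobox gene, from 18.9 ± 0.973 to 0.963 ± 0.0859 CPM (log2 fold changes -4.64 and -4.28). BEST1, a chloride channel gene that overlaps the ferritin gene FTH1 on the other strand, rose from 0.147 ± 0.170 to 13.5 ± 0.422 CPM. C19orf35 had 0 counts in the DMSO libraries and 185 in the THZ1 libraries, at least 86.4-fold higher, against a floor of 3 counts over the group. Such floors and intervals cover counting error only.

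MYC lies on chromosome 8 from 127735434 to 127741434, HOMEZ on chromosome 14 from 23272422 to 23299447, and BEST1 on chromosome 11 from 61949821 to 61965515. The other large rises were those of RNA45S5 (7.57), RNA28S5 (4.95), which is mature 28S ribosomal RNA, SLC7A5P2 (4.24) and the antisense transcript UCKL1-AS1 (3.48), as log2 fold changes. The ribosomal genes and the pseudogene have near-identical copies, and reads of BEST1 and UCKL1-AS1 cannot be told from those of FTH1 and UCKL1 without strand. The other large falls were those of KLHL26 (-4.05), ZBED5 (-3.99), ZSCAN26 (-3.84) and ZNF691 (-3.82).

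Housekeeping genes rose in Panc327 as well. The correlation of fold change with expression level was 0.349 there, and its part in these lists and the ZNF list was not tested. All 78 ribosomal protein genes rose (78 adjusted over the list alone) with a median of 1.02, led by RPL12 (1.37) and RPL39 (1.26), with camera adjusted p = 7.87e-39 and adjusted p = 0.0453 with an estimated correlation. Of 56 respiratory chain genes 55 rose and 0 fell (the same adjusted over the list alone), led by COX8A (1.37) and COX6C (1.33), with a median of 0.97 (adjusted p = 0.0177 with an estimated correlation). Of 24 glycolysis genes 18 rose and 5 fell (19 and 5 adjusted over the list alone), with ALDOC at 1.13 and TPI1 at 1.02. The camera adjusted p was 3.52e-05, and adjusted p = 0.0983 with an estimated correlation. Of 15 reference genes 12 rose and 3 fell, over all genes and over the list alone, from B2M (1.17) to TBP (-1.79), with camera adjusted p = 2.29e-05 and adjusted p = 0.0809 with an estimated correlation. Of 22 replication histone genes, whose main transcripts lack a poly(A) tail, 17 rose and 0 fell (the same adjusted over the list alone). HIST2H2BE (1.47), HIST1H1C (1.22) and HIST1H2BK (0.89) were among them (adjusted p = 0.0198 with an estimated correlation). With libraries scaled by size alone, the medians in Panc327 were 0.65 for respiratory chain genes, 0.36 for glycolysis genes (14 higher, 9 lower) and 0.51 for reference genes, in place of 0.97, 0.69 and 0.83.

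Of 35 mitotic genes 27 fell and 4 rose (28 and 4 adjusted over the list alone), with a median of -0.70, among them the kinases AURKA (-2.82) and TTK (-2.70) and the centromeric histone CENPA (-2.04). The list stood below other genes (camera adjusted p = 2e-07, adjusted p = 0.0453 with an estimated correlation). Of 37 ribosome biogenesis genes 26 fell and 6 rose, over all genes and over the list alone, including GNL3 (-2.68), RRS1 (-2.66) and NOP16 (-2.06). The camera adjusted p was 0.000359, and adjusted p = 0.0845 with an estimated correlation. Of 408 ZNF genes 340 fell and 19 rose (341 and 20 adjusted over the list alone), with a median of -1.46. ZNF691 (-3.82), ZNF772 (-3.73) and ZNF202 (-3.48) fell and ZNF460 rose (2.03). The list kept its call (adjusted p = 0.000169 with an estimated correlation). Of 35 recombination and Fanconi anaemia genes 23 fell and 8 rose, over all genes and over the list alone, with PALB2 at -2.58 and BRCA2 at -2.01 (camera adjusted p = 0.0227, adjusted p = 0.184 with an estimated correlation). With libraries scaled by size alone, the medians were -0.9 for ribosome biogenesis genes and -0.68 for repair genes, in place of -0.57 and -0.36.

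Of 24 lineage transcription factors 14 fell in Panc327 and 2 rose, over all genes and over the list alone, with SOX2 at -2.28, FOSL1 at -2.12 and RUNX3 at -1.22 (camera adjusted p = 0.0227, adjusted p = 0.114 with an estimated correlation). Of 20 NF-kB target genes 15 fell and 2 rose, over all genes and over the list alone. The pathway's inhibitors NFKBIE (-1.57) and NFKBIA (-1.40) fell, as did its subunit RELB (-1.27), with camera adjusted p = 0.0413 and adjusted p = 0.292 with an estimated correlation. Of 35 immediate early genes 20 fell and 10 rose (21 and 10 adjusted over the list alone). The phosphatases DUSP6 (-3.25) and DUSP5 (-2.16) and the matricellular gene CYR61 (-2.41) fell, while FOS (2.44), ID2 (1.94) and JUNB (1.59) rose, and the list as a whole did not pass (camera adjusted p = 0.0652). Of 18 mesenchymal genes 13 rose and 2 fell, over all genes and over the list alone, with COL5A1 and FBN1 at 1.06 each and the transcription factor SNAI2 at -1.80 (camera adjusted p = 0.00222, adjusted p = 0.0983 with an estimated correlation). The mesenchymal median of 0.73 came to 0.43, and the immediate early median of -0.53 moved further down, with libraries scaled by size alone (8 higher, 24 lower).

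Stress genes of Panc327 moved in both directions. Of 37 integrated stress response genes 16 rose and 14 fell (16 and 14 adjusted over the list alone), and the median of 0.08 did not stand apart (limma camera adjusted p = 0.663). It turned to -0.25 when libraries were scaled by size alone. ATF4 fell from 359 ± 11.2 to 270 ± 8.75 CPM (SD, n = 3; log2 fold change -0.41, SE 0.04, edgeR adjusted p = 9.27e-15). ASNS (0.97), the serine synthesis enzyme PHGDH (0.94) and the cystine transporter SLC7A11 (0.93) rose. SESN2 (-2.36), DDIT3 (-2.11), DDIT4 (-1.51) and TRIB3 (-1.50) fell, and CHAC1 was at 0.08 (edgeR adjusted p = 0.692). ATF3 passed at 0.35 (edgeR adjusted p = 0.0143), but came to 0.27 without DMSO replicate 1 and to 0.02 with libraries scaled by size alone, and passed under neither. Of 23 unfolded protein response targets 14 rose and 9 fell, over all genes and over the list alone, with PDIA3 at 1.03, XBP1 at -3.27 and DNAJB9 at -1.90. The camera adjusted p was 0.0413, and adjusted p = 0.313 with an estimated correlation. The median of 0.24, against a mean of 0.00, turned to -0.09 when libraries were scaled by size alone. Of 19 heat shock genes 11 rose and 4 fell, over all genes and over the list alone, with HSPA1B at 1.92 and HSPA8 at -1.55 (camera adjusted p = 0.0413, adjusted p = 0.332 with an estimated correlation). Scaled by library size alone, 8 were higher and 9 lower, and the median of 0.39 came to 0.07. Of 12 RNA polymerase II subunit genes 9 rose and 2 fell, over all genes and over the list alone (camera adjusted p = 0.0145, adjusted p = 0.0983 with an estimated correlation), and their median of 0.75 came to 0.42 with scaling by library size alone.

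CDK7 fell in Panc327 from 40.0 ± 0.921 to 12.3 ± 2.45 CPM, CDK12 from 137 ± 2.66 to 62.3 ± 2.71 CPM and CDK13 from 97.3 ± 4.05 to 77.1 ± 5.77 CPM (SD, n = 3). SIRT6 fell from 9.53 ± 1.01 to 6.13 ± 0.362 CPM (log2 fold change -0.63, SE 0.18, edgeR adjusted p = 0.000973), and MCL1 fell by 0.69 on the log2 scale. HEXIM1 passed the test at 0.35 (SE 0.06), but not at 0.02 when libraries were scaled by size alone. THZ1 changed 10283 genes in Panc327, 4992 higher and 5291 lower, and 1077 and 2662 of these at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Scaling by library size alone took the median of all genes from -0.01 to -0.34, and 31.0% of the calls were then higher in place of 48.5%.

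In SUIT2, HEXIM1 rose with THZ1 from a DMSO level of 59.4 ± 2.62 CPM (SD, n = 3; log2 fold change 1.05, SE 0.06, edgeR adjusted p = 7.54e-27) and POLR2A from 296 ± 1.23 to 565 ± 6.74 CPM (0.93, SE 0.04). KRCC1 fell from 15.2 ± 2.30 to 5.81 ± 0.995 CPM and PPP1R10, a nuclear regulatory subunit of protein phosphatase 1, from 116 ± 4.48 to 57.2 ± 0.550 CPM (log2 fold changes -1.38 and -1.02). RNA45S5 rose by 1.82 on the log2 scale, VAMP1 by 0.99, the RNA-binding gene RBM15 by 0.82 and ANKRD18A by 0.82. The antisense transcript CTBP1-AS2 (-1.10), the recombination factor SFR1 (-1.02), KLHL22 (-0.97) and C21orf58 (-0.95) fell. KRCC1 lies on chromosome 2 from 88027205 to 88055729 and PPP1R10 on chromosome 6 from 30600400 to 30618612.

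Of the lists that stood apart in SUIT2 by camera, none kept its call with an estimated correlation. Respiratory chain genes had 13 of 56 higher and 0 lower (15 and 0 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 8.24e-06, adjusted p = 0.264 with an estimated correlation). Ribosomal protein genes had 5 of 78 higher and 0 lower (3 and 0 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 7.78e-06, adjusted p = 0.587 with an estimated correlation). Of 35 immediate early genes 11 rose and 4 fell, over all genes and over the list alone, with JUNB at 0.57, IER5 at 0.52, TIPARP at -0.60 and FOSL1 at -0.47 (camera adjusted p = 0.0469, adjusted p = 0.5 with an estimated correlation). Of 23 p53 targets 4 rose and 0 fell, over all genes and over the list alone, among them FDXR (0.54) and CCNG1 (0.27), with camera adjusted p = 0.0411 and adjusted p = 0.264 with an estimated correlation. Of 24 glycolysis genes 6 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.0409, adjusted p = 0.5 with an estimated correlation). Of 12 RNA polymerase II subunit genes 2 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.0499, adjusted p = 0.288 with an estimated correlation). Of 37 ribosome biogenesis genes 1 rose and 6 fell (1 and 6 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.0499, adjusted p = 0.5 with an estimated correlation). Of 35 mitotic genes 10 fell and 1 rose (12 and 3 adjusted over the list alone), including HMMR (-0.29) and CDC20 (-0.26), with camera adjusted p = 0.0499 and adjusted p = 0.5 with an estimated correlation. Of 24 lineage transcription factors 4 fell and 2 rose (6 and 3 adjusted over the list alone), with the intestinal factor CDX2 at -0.58, EHF at -0.41 and SOX9 at 0.38 (camera adjusted p = 0.0374, adjusted p = 0.264 with an estimated correlation). Of 408 ZNF genes 25 fell and 11 rose (23 and 6 adjusted over the list alone), with camera adjusted p = 0.508.

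Of 37 integrated stress response genes in SUIT2, 3 rose and 5 fell (4 and 5 adjusted over the list alone), with a median of -0.02 (camera adjusted p = 0.549). ATF4 fell from 240 ± 5.10 to 184 ± 2.71 CPM (SD, n = 3; log2 fold change -0.38, SE 0.04), the amino acid transporter SLC7A5 fell (-0.40), as did STC2 (-0.36) and DDIT3 (-0.34). ATF3 passed at 0.88 (SE 0.27, edgeR adjusted p = 0.0153), but not without DMSO replicate 1 (0.82), DMSO replicate 2 (0.74) or THZ1 replicate 3 (0.58). ASNS was at 0.18 (edgeR adjusted p = 0.125), and at 0.25 (edgeR adjusted p = 0.0453) without THZ1 replicate 1. CHAC1 (-0.23), TRIB3 (-0.19) and SESN2 (0.08) did not pass. CDK12 rose (0.31), MCL1 rose (0.18) and MYC fell (-0.19), while CDK7 (0.17), CDK13 (0.07) and SIRT6 (0.09) did not pass. THZ1 changed 2044 genes in SUIT2, 974 higher and 1070 lower, and 20 and 63 of these at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). DESeq2 called 603 genes higher, and the edgeR test without DMSO replicate 3 called 642.

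**Figure D2:**
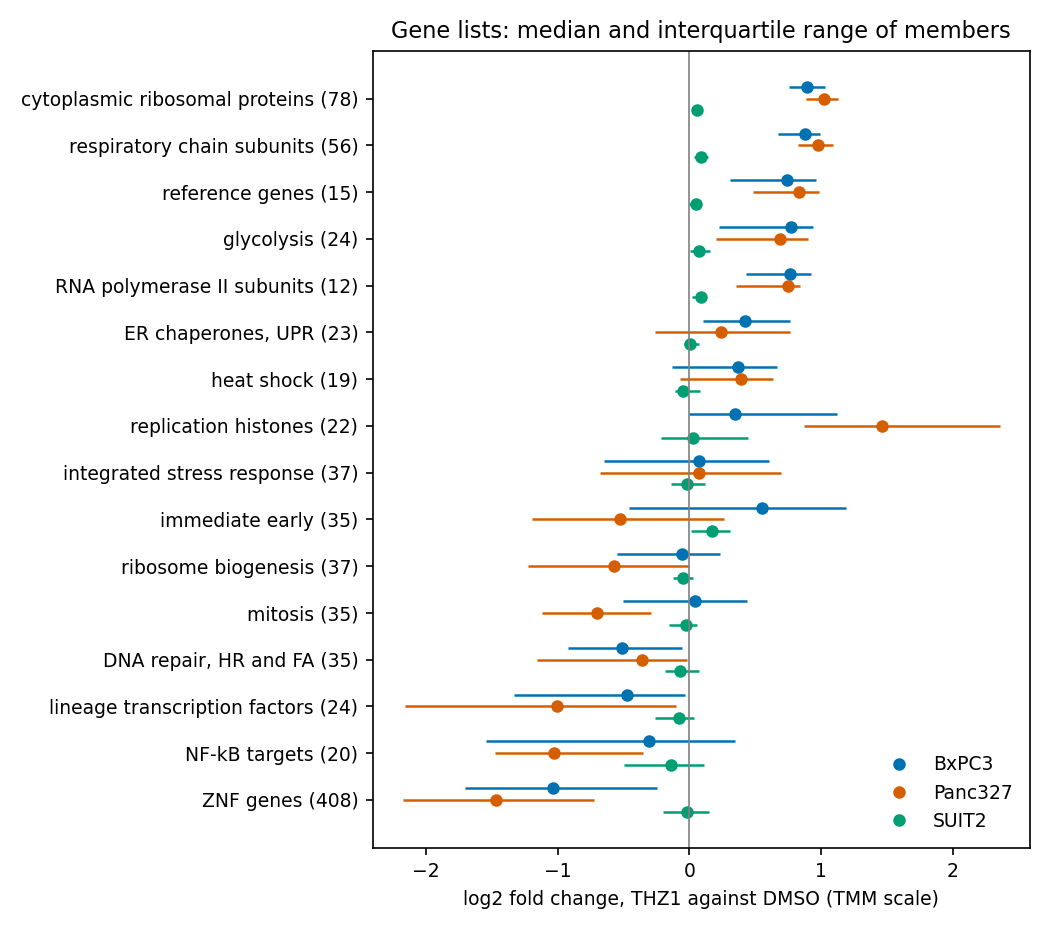
Median (point) and interquartile range (line) of the log2 fold change with THZ1 over the members of 16 gene lists in the 3 lines, with the number of members tested in parentheses. Ribosomal protein genes had medians of 0.89 in BxPC3, 1.02 in Panc327 and 0.05 in SUIT2. Scaled by library size alone, the heat shock median of BxPC3, the unfolded protein response median of Panc327 and the stress response medians of both lines were below 0.

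Immediate early genes responded differently in BxPC3 and Panc327, by a median of 1.003 on the log2 scale, BxPC3 minus Panc327. Of 35 members 27 had a higher log2 fold change in BxPC3 and 0 a lower one (28 and 1 adjusted over the list alone; camera adjusted p = 6.48e-15, adjusted p = 0.00521 with an estimated correlation). Replication histones had a median difference of -1.14, with 6 of 22 lower in BxPC3 and 1 higher (6 and 1 adjusted over the list alone; camera adjusted p = 0.0458, adjusted p = 0.0984 with an estimated correlation). The histone list did not pass camera with scaling by library size alone (adjusted p = 0.121), with RLE size factors (0.132), or without any 1 of 7 of the 12 libraries, among them Panc327 DMSO replicate 2 (0.167). Mitotic genes differed by a median of 0.61, with 29 of 35 higher in BxPC3 and 1 lower (30 and 1 adjusted over the list alone), and ribosome biogenesis genes by 0.46, with 32 of 37 higher and 1 lower (33 and 2 adjusted over the list alone). Both had adjusted p = 0.00521 with an estimated correlation. ZNF genes differed by 0.45, with 143 of 408 higher and 25 lower (148 and 26 adjusted over the list alone; adjusted p = 0.0414 with an estimated correlation). The share of records aligned to several places was 9.97 percentage points higher with THZ1 than with DMSO in BxPC3 and 39.2 points higher in Panc327.

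Among single genes, SESN2 differed by 2.66 (SE 0.21, edgeR adjusted p = 4.85e-19), MYC by 1.56 (SE 0.08), SIRT6 by 1.28 (SE 0.21, adjusted p = 4.77e-07), CDK7 by 1.11 (SE 0.15) and ATF4 by 0.80 (SE 0.06), all as BxPC3 minus Panc327. POLR2A differed by 0.90, HEXIM1 by 0.56 and CHAC1 by -1.29. ASNS (0.01, edgeR adjusted p = 0.966) and DDIT3 (-0.31, edgeR adjusted p = 0.63) did not pass. The 10 genes with the largest fitted differences each had a group with 0 counts, so no fold is given. The lipid transport gene APOE had 0 counts with DMSO and 15 with THZ1 in BxPC3, and 487 and 649 in Panc327. C19orf35 had 6 and 12 counts in BxPC3, and 0 and 185 in Panc327. CDH13 had 4 and 0 counts in BxPC3, and 3461 and 4363 in Panc327, and its call was lost without BxPC3 DMSO replicate 2 (-4.16) or without BxPC3 THZ1 replicate 1 (-4.55), 2 (-4.55) or 3 (-4.54). The difference passed in 5088 genes, 3110 of them with the higher log2 fold change in BxPC3 and 1978 in Panc327, a split of 61.1%. It was 50.8% with scaling by library size alone and 49.6% with RLE size factors.

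Between BxPC3 and SUIT2, DDIT3 differed by -2.08 (SE 0.26, edgeR adjusted p = 4.57e-11), CDK12 by -0.88 (SE 0.08), ASNS by 0.80 (SE 0.11), ATF4 by 0.78 (SE 0.06) and CDK7 by -0.78 (SE 0.13), as BxPC3 minus SUIT2. SIRT6 differed by 0.56 (edgeR adjusted p = 0.00257), and by 0.18 (edgeR adjusted p = 0.377) with scaling by library size alone. HEXIM1 did not pass at -0.15 (edgeR adjusted p = 0.127), but passed at -0.52 with scaling by library size alone and at -0.22 without BxPC3 DMSO replicate 1. All 78 ribosomal protein genes had the higher log2 fold change in BxPC3 (78 adjusted over the list alone), by a median of 0.81, as did 55 of 56 respiratory chain genes (55 adjusted over the list alone), by 0.76. These lists held with adjusted p = 0.0424 and adjusted p = 0.015 with an estimated correlation. ZNF genes differed by -0.99, 223 of 408 lower and 33 higher (224 and 35 adjusted over the list alone; adjusted p = 0.00215 with an estimated correlation), and reference genes by 0.69, 13 of 15 higher and 2 lower (13 and 2 adjusted over the list alone; adjusted p = 0.0424 with an estimated correlation). With scaling by library size alone, the medians came to 0.43 for ribosomal protein, 0.38 for respiratory chain and 0.31 for reference genes. Among the genes with the largest differences, RNA45S5 differed by 6.70 (SE 0.30) and LSMEM1 by 4.05 (SE 0.57). LINC00926, SH2D2A and IL1B each had a group of at most 3 counts, so no fold is given. The cytokine gene IL1B had 3142 counts with DMSO and 533 with THZ1 in BxPC3, and 0 and 2 in SUIT2. Its call was lost without SUIT2 DMSO replicate 1 (-4.53), 2 (-4.53) or 3 (-4.52), or without SUIT2 THZ1 replicate 1 (-4.23) or 2 (-4.14). The difference passed in 7694 genes, with 49.7% of them higher in BxPC3 and 22.8% with scaling by library size alone. That scaling took the median difference of all genes from 0.00 to -0.35, so differences above 0, such as those of ASNS and ATF4, are smaller with it.

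Between Panc327 and SUIT2, SESN2 differed by -2.44 (SE 0.22, edgeR adjusted p = 1.2e-17), MYC by -1.90 (SE 0.08), CDK7 by -1.89 (SE 0.14), DDIT3 by -1.77 (SE 0.28) and CDK12 by -1.45 (SE 0.08), as Panc327 minus SUIT2. SIRT6 differed by -0.73 (SE 0.21, edgeR adjusted p = 0.00193) and HEXIM1 by -0.70 (SE 0.09). ATF4 did not pass at -0.02 (edgeR adjusted p = 0.769), but passed at -0.33 with scaling by library size alone. All 78 ribosomal protein genes were higher in Panc327 (78 adjusted over the list alone), by a median of 0.94, and 55 of 56 respiratory chain genes (55 adjusted over the list alone), by 0.84, with adjusted p = 0.0229 and adjusted p = 0.00797 with an estimated correlation. The medians came to 0.635 and 0.533 with scaling by library size alone. Mitotic genes differed by -0.63 (-0.94 with that scaling), 27 of 35 lower and 2 higher (28 and 2 adjusted over the list alone; adjusted p = 0.0406 with an estimated correlation), and ZNF genes by -1.38, 297 of 408 lower and 15 higher (300 and 17 adjusted over the list alone; adjusted p = 0.000286 with an estimated correlation). Among the genes with the largest differences were BEST1 (6.2, SE 1.03), RNA45S5 (5.75, SE 0.25), RNA28S5 (4.70, SE 0.44), KLHL26 (-4.19, SE 0.34) and PARS2 (-4.11, SE 0.45). COL4A1, SNCG and BICC1 each had a group of at most 1 count, so no fold is given. The basement membrane gene COL4A1 had 37377 counts with DMSO and 40894 with THZ1 in Panc327, and 34 and 1 in SUIT2. The difference passed in 8507 genes, with 46.7% of them higher in Panc327 and 28.1% with scaling by library size alone.

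**Figure D3:**
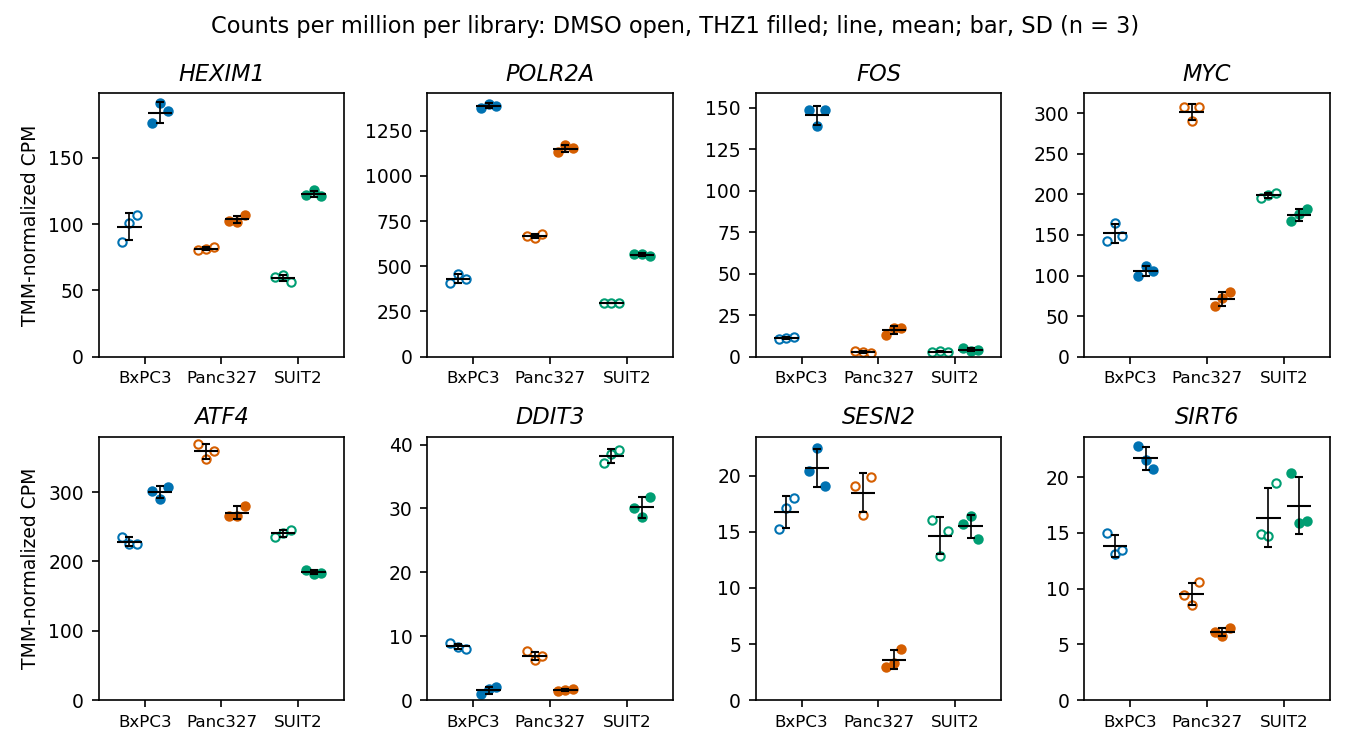
TMM-normalised CPM of 8 genes per library (points, DMSO open and THZ1 filled) with the mean (line) and SD (bar, n = 3) in each line. MYC fell from 302 to 71.3 CPM in Panc327 and from 152 to 106 CPM in BxPC3. With libraries scaled by size alone, ATF4 and SESN2 in BxPC3 and HEXIM1 in Panc327 did not pass the test.

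Responses were closest between BxPC3 and Panc327. Across 14011 genes the log2 fold changes of that pair had a Pearson correlation of 0.633 and a Spearman correlation of 0.695, against 0.217 and 0.361 for BxPC3 and SUIT2 and 0.124 and 0.213 for Panc327 and SUIT2. Genes are not independent replicates, so no p is given for these correlations or for the shared calls. BxPC3 and Panc327 shared 3659 genes called higher, where independent lists would share 1759, and 3678 called lower, where they would share 1807, while 440 genes called higher in BxPC3 were called lower in Panc327 and 168 called lower in BxPC3 were called higher in Panc327. BxPC3 and SUIT2 shared 677 genes called higher (343 if independent) and 781 called lower (365 if independent), while 102 higher in BxPC3 were lower in SUIT2 and 117 the reverse. Panc327 and SUIT2 shared 547 called higher (347 if independent) and 654 called lower (404 if independent), while 151 higher in Panc327 were lower in SUIT2 and 263 the reverse. The 3659 genes that rose in both BxPC3 and Panc327 had a median of 0.07 in SUIT2, where 507 of them were called higher and 71 lower.

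With DMSO, the lines differed in subtype and lineage genes. All 23 basal-like pancreatic cancer genes were higher in BxPC3 than in SUIT2 (23 adjusted over the list alone), with a median log2 difference of 6.89 (camera adjusted p = 6.88e-10, adjusted p = 0.01 with an estimated correlation). KRT17, a basal keratin, was at 2516 ± 31.2 CPM in BxPC3, 1293 ± 53.8 in Panc327 and 1.11 ± 0.706 in SUIT2 (SD, n = 3). VIM, the mesenchymal intermediate filament vimentin, was at 17.5 ± 2.85, 0.935 ± 0.955 and 1603 ± 63.5 CPM. GATA6, an endodermal transcription factor, was at 55 ± 3.54, 1.28 ± 0.295 and 38.3 ± 2.51 CPM. Each pairwise difference of KRT17, VIM and GATA6 passed the edgeR test, except that the difference of KRT17 between BxPC3 and Panc327 did not pass with DESeq2 (adjusted p = 0.149). KRT17 lies on chromosome 17 from 41619441 to 41624842, VIM on chromosome 10 from 17228259 to 17237593, and GATA6 on chromosome 18 from 22169443 to 22202528.

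Between Panc327 and SUIT2, 21 of 23 basal-like genes were higher and 1 lower (the same adjusted over the list alone), with a median of 6.33 (camera adjusted p = 1.82e-06, adjusted p = 0.0523 with an estimated correlation). Between BxPC3 and Panc327, 14 of 23 were higher and 4 lower (the same adjusted over the list alone; camera adjusted p = 0.00749, adjusted p = 0.203 with an estimated correlation). Lineage transcription factors were lower in Panc327 than in SUIT2, 19 of 24 with 4 higher (the same adjusted over the list alone), by a median of -2.44 (camera adjusted p = 0.000369, adjusted p = 0.0523 with an estimated correlation). Of 23 interferon response genes 21 were higher and 2 lower in BxPC3 than in Panc327 (the same adjusted over the list alone), by a median of 2.49 (camera adjusted p = 3.58e-05, adjusted p = 0.203 with an estimated correlation). Of 37 integrated stress response genes 26 were lower in BxPC3 than in Panc327 and 6 higher (camera adjusted p = 0.0172, adjusted p = 0.149 with an estimated correlation), and 24 were higher in Panc327 than in SUIT2 and 8 lower (camera adjusted p = 0.0255, adjusted p = 0.0788 with an estimated correlation), with the same counts adjusted over the list alone. SIRT6 was at 13.8 ± 0.989 CPM in BxPC3, 9.53 ± 1.01 in Panc327 and 16.4 ± 2.65 in SUIT2 (SD, n = 3). Panc327 was lower than BxPC3 (log2 difference of BxPC3 minus Panc327 0.54, SE 0.13, edgeR adjusted p = 0.000129) and lower than SUIT2 (-0.79, SE 0.13, adjusted p = 2.26e-08). The difference of BxPC3 minus SUIT2 (-0.25, adjusted p = 0.0446) was lost with DESeq2 (adjusted p = 0.119), limma voom (0.0586), RLE size factors (0.0561), only the lines compared (0.056) and no filter (0.0512), without BxPC3 DMSO replicate 2 (-0.22) or 3 (-0.23) and without SUIT2 DMSO replicate 3 (-0.10).

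The largest DMSO differences were in genes with 0 or 1 counts in 1 line, and folds for 0 counts are against a floor of 3 counts over the group. Thrombomodulin (THBD) was at least 2970-fold higher in BxPC3 than in Panc327, and the cancer-testis antigens MAGEA3 and MAGEA1 at least 1000-fold and at least 817-fold higher. Reads of the MAGEA genes are uncertain because the family's members are similar. The kallikrein KLK5 and DKK3 were at least 3510-fold and at least 1460-fold higher in Panc327 than in BxPC3. Tenascin C (TNC) had 29791 counts in Panc327 and 1 in BxPC3, a ratio of 28200 (95% counting interval 5060 to 1110000). SCEL, HCLS1 and TMEM30B were at least 1260-fold, at least 1240-fold and at least 1000-fold higher in BxPC3 than in SUIT2, and the chloride channel gene CFTR, IGFBP3 and PKDCC at least 2220-fold, at least 1300-fold and at least 1170-fold higher in SUIT2. QPCT and TDRD1 were at least 1030-fold and at least 872-fold higher in Panc327 than in SUIT2, and PTPRZ1 had 9327 counts against 1, a ratio of 8400 (95% counting interval 1510 to 332000). NR5A2, SDPR and NNMT were at least 713-fold, at least 618-fold and at least 617-fold higher in SUIT2 than in Panc327. Differences with DMSO passed in 11107 genes between BxPC3 and Panc327, 11007 between BxPC3 and SUIT2 and 11553 between Panc327 and SUIT2, and 4747, 4846 and 5559 of these were at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05).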

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

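The 6 tests of ribosomal RNA and of the small SUIT2 response, and all counts of other splits of the libraries, were chosen after the results were seen; the 3 tests of gene span were chosen before, and the second of them was changed afterwards.

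The response to THZ1 differed between lines by a test of the difference itself. It passed in 5088 genes between BxPC3 and Panc327, 7694 between BxPC3 and SUIT2 and 8507 between Panc327 and SUIT2. Of 60 splits of the libraries, 5 gave as many genes as the real one for BxPC3 and Panc327 (highest other 7074), so chance is not excluded for that count by this test. For BxPC3 and SUIT2 4 did (highest other 7961), and chance is not excluded either. For Panc327 and SUIT2 only 1, the real one, did (highest other 8379). All 4 and 3 other splits that gave as many kept the real treatment split of 1 line. In each pair, splits that kept neither line's gave at most 0 genes. A split that keeps 1 line's sets a real response against a mixed one, so its count reflects a treatment effect. Comparing the real count with such counts does not test whether the difference between lines arose by chance. Chance is therefore not excluded for Panc327 and SUIT2 either.

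Between BxPC3 and Panc327, the median difference of the log2 fold change was 1.003 for immediate early genes, 0.613 for mitotic genes, 0.462 for ribosome biogenesis genes and 0.45 for numbered zinc finger (ZNF) genes. Single genes that differed were CDK7 (1.11), CDK12 (0.56), CDK13 (0.56), SIRT6 (1.28), ATF4 (0.8), ATF3 (1.05), CHAC1 (-1.29), TRIB3 (0.46), SESN2 (2.66), MYC (1.56), MCL1 (0.29), HEXIM1 (0.56) and POLR2A (0.9). The call of TRIB3 was lost without BxPC3 THZ1 replicate 1 (0.33), with DESeq2 (0.38) and with only the lines compared (0.33). Between BxPC3 and SUIT2, the medians were 0.811 for ribosomal protein genes, 0.764 for respiratory chain genes and -0.989 for ZNF genes. Single genes were RNA45S5 (6.7), LSMEM1 (4.05), CDK7 (-0.78), CDK12 (-0.88), SIRT6 (0.56), ATF4 (0.78), DDIT3 (-2.08), ASNS (0.8), TRIB3 (-0.85), MYC (-0.34), MCL1 (-0.58) and POLR2A (0.75).

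Between Panc327 and SUIT2, the medians were -0.629 for mitotic genes, 0.945 for ribosomal protein genes, 0.842 for respiratory chain genes and -1.378 for ZNF genes. Single genes were BEST1 (6.2), RNA45S5 (5.75), RNA28S5 (4.7), KLHL26 (-4.19), PARS2 (-4.11), CDK7 (-1.89), CDK12 (-1.45), CDK13 (-0.41), SIRT6 (-0.73), DDIT3 (-1.77), ASNS (0.79), TRIB3 (-1.31), SESN2 (-2.44), MYC (-1.9), MCL1 (-0.87), HEXIM1 (-0.7) and POLR2A (-0.15). The call of POLR2A was lost without Panc327 DMSO replicate 2 (-0.07), and with RLE size factors or DESeq2 (-0.03 each). The biological difference between these lines that the design names, the line itself, stays open and untested.

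Records aligned to several places were 22.8% in BxPC3 and 52.8% in Panc327 with THZ1, against 12.8% and 13.6% with DMSO. Reads outside annotated genes per 100 gene reads were 14.5 and 22.8, against 12.1 and 14.7. As a share of all records they did not rise in both lines: they went from 9.30% to 9.65% in BxPC3 and from 10.97% to 8.62% in Panc327, where gene reads were a smaller share. Ribosomal RNA genes rose in the same libraries. Genomic DNA stays open. Reads outside genes per gene read rose by at most 0.0102 of the factor by which RNA45S5 rose in CPM scaled by library size alone, but that test is void. Even 0.1 of that factor would have needed 341 and 224 reads outside genes per 100 gene reads, because RNA45S5 started so low. Added RNA of 1 fixed ribosomal profile stays open for BxPC3 and Panc327. Their added RNA45S5 per added RNA28S5 differed by a factor of 1.17 (5.64 and 6.6). SUIT2 was not in that test. RNA45S5 rose there too, from 4.45 to 15.7 CPM scaled by library size alone. The share of records aligned to several places did not rise with it (12.9% with THZ1, 13.2% with DMSO). RNA28S5 in SUIT2 was at 35.8 ± 17.0 CPM with THZ1 and 30.8 ± 13.5 with DMSO (SD, n = 3). That spread is too large to give SUIT2 a ratio of added RNA. RNA without a poly(A) tail that was kept in the THZ1 libraries stays open, since the smaller replication histone median was 0.344, above 0, but that list passed the threshold with an estimated correlation only in Panc327. The design does not separate a larger share of ribosomal RNA in the cells from a poorer poly(A) selection.

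SUIT2 responded less than the other lines. The smaller log2 fold change of HEXIM1 and POLR2A in SUIT2 was 0.93, and both were called, which met the bound against a swap for untreated cells. Both are among the 6 largest rises listed for SUIT2, and the bound was set after their values were seen, so that test decides nothing. A swap is argued against by the calls that SUIT2 shared with BxPC3. They were 677 higher and 781 lower, where independent lists would share 343 and 365. A larger spread is argued against as the whole cause, because the median absolute log2 fold change in SUIT2 was at most 0.197 of that in either other line (0.104 against 0.531 and 0.607). A SUIT2 response that is the BxPC3 or Panc327 response with 1 scaling for every gene is argued against too. Of 2044 genes called in SUIT2, 219 went the opposite way in BxPC3 and 414 in Panc327. The threshold allows 102 false SUIT2 calls, and false calls of the other line were not counted. The smallest such ratio over 3 scalings of the libraries was 2.07. These counts do not speak for or against a lower effective dose. BxPC3 and Panc327, at the same dose, also had 440 and 168 genes called in opposite directions. A lower effective dose was not tested and stays open, as does resistance of the line.

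Fold changes were set against genomic span, as a stop of transcription within the treatment time could lower long genes more. A loss that grows with span is argued against: the Spearman correlation was -0.0699 in BxPC3 and -0.00363 in Panc327, the larger value. Levels of poly(A) RNA also hold RNA made before treatment, so these correlations do not test a stop of transcription itself. Genes under 10 kb did have the highest median, 0.29 in BxPC3 and 0.253 in Panc327. Medians for 10 to 30 kb, 30 to 100 kb and over 100 kb were 0.135, 0.0533 and 0.0973 in BxPC3, and -0.0404, -0.031 and 0.115 in Panc327, with no further fall in the longest genes. Why the shortest genes stood higher was not tested. The second test asked whether transcript length, GC content or expression stand in for span. In its first form it asked how much of the correlation with span was kept: 122% in BxPC3 by size, which met the bound written beforehand against that explanation. That bound ignored the sign, and the correlations after removal were positive, 0.0855 in BxPC3 and 0.154 in Panc327. The test was changed after this was seen, and decides nothing, since there was no steady relation to span to replace. The third test asked about intronic or genomic reads as the cause of a relation to span. The median of single-exon genes minus that of multi-exon genes was -0.738 in BxPC3 and -0.985 in Panc327, which met the bound written beforehand against them. It decides nothing either, since there was no steady relation to span to explain. Single-exon genes also have no introns, so added intronic reads would not raise them. Fold changes were correlated with expression at 0.398 in BxPC3 and 0.349 in Panc327, and with transcript length at -0.233 and -0.196. Neither was weighed further.

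Within a line, 10 splits of 6 libraries are too few for a share under 0.05. The real counts of genes higher and lower were 4938 and 4784 in BxPC3 and 4992 and 5291 in Panc327 (highest other 0), and 974 and 1070 in SUIT2 (highest other 1), with 1 split of 10 as large in each. With DMSO the counts were 11107, 11007 and 11553 (highest other 0; 1 split as large in each). The absolute median of the integrated stress response list was 0.0706 in BxPC3 (highest other 0.0656; 1 split as large), 0.0756 in Panc327 (highest other 0.0897; 2 splits) and 0.0167 in SUIT2 (highest other 0.0474; 5 splits). Lists called numbered 9, 15 and 9 in BxPC3, Panc327 and SUIT2 (highest other 10, 14 and 9; 2, 1 and 2 splits). These are camera calls with the preset correlation, and other splits called lists too. The number of lists called thus did not set the real split apart in BxPC3 or SUIT2. Every other split within a line holds an uneven mix of both treatments in each group, so part of a treatment effect remains in it. The numbers of lists called therefore do not test whether the list calls arose by chance. Why other splits called lists was not tested. The correlations of responses of 0.633, 0.217 and 0.124 were exceeded by 0 of the other splits among 60. In each pair 1 split was as large, the real one (highest other 0.448, 0.151 and 0.0937). Every other split drawn mixed both treatments in the groups of at least 1 line, which weakens a real response. The ranking therefore does not test whether the agreement between lines arose by chance, and chance is not excluded by it.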

How the results depend on the processing

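The alternatives reported here were chosen before the data were examined. With scaling by library size alone, 2601 genes were higher in BxPC3 and 3170 in Panc327, since it lowers the median gene. The same scaling reversed the heat shock median in BxPC3 (-0.029), the unfolded protein response median in Panc327 (-0.089) and its difference between Panc327 and SUIT2 (-0.078), and took the replication histone median of BxPC3 from 0.344 to 0. Among genes it reversed CDK13 in BxPC3 (-0.18) and its difference from SUIT2 (-0.23), SESN2 in BxPC3 (-0.1), and took ATF4 in BxPC3 to 0.

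DESeq2 called 603 genes higher in SUIT2, and the cause was not tested. A threshold of 2-fold left 803 higher and 2109 lower in BxPC3, 1077 and 2662 in Panc327 and 20 and 63 in SUIT2. It left 1292, 2094 and 3129 differences of responses and 4747, 4846 and 5559 DMSO differences, by its own construction. Fry, which tests a list by itself and not against other genes, called the integrated stress response list in BxPC3 (0.071, adjusted p = 3.29e-07) and Panc327 (0.076, adjusted p = 7.04e-05). Over genes with at least 10 CPM the correlations of responses were 0.751, 0.271 and 0.171. The cause was not tested.

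Leaving out each library in turn, genes higher ranged from 4700 to 4755 in BxPC3, 4746 to 5290 in Panc327 and 642 (without SUIT2 DMSO replicate 3) to 790 in SUIT2. Genes lower ranged from 4482 to 4653, 4785 to 5195 and 741 to 901. The integrated stress response median, which passed in no case, ranged from 0 (without BxPC3 THZ1 replicate 1) to 0.148 (without DMSO replicate 2) in BxPC3. It ranged from 0.009 (without Panc327 THZ1 replicate 3) to 0.185 (without DMSO replicate 2) in Panc327, and from -0.014 to 0.005 in SUIT2. With a replicate block (paired by number) the counts were 4890 and 4746, 4957 and 5264, and 907 and 1013. DMSO and THZ1 libraries of the same number in a line, as deviations from their group means, had correlations of -0.171 to 0.0503, and those of different numbers -0.075 to 0.139, so no pairing by number was seen. RLE size factors, no filter, limma voom and only the lines compared left each of the counts of genes within 1.5 times its value. Scaling to mitochondrially encoded genes was not run. Of the list tests of THZ1 and of differences of responses, 45 lost their call with an estimated correlation; the DMSO list tests are not in this count. Of the named genes, 9 lost their call with DESeq2 and 3 with limma voom. Of named genes and lists, 11 lost it and 16 gained it with library size only, and 7 whose sign changed are counted apart. Among those 7, ATF4 and SESN2 in BxPC3 also lost their call.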

Other observations

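The markers of other cell types were written before the data were examined, and 8 of 11 fibroblast, 9 of 11 leukocyte and 7 of 9 endothelial markers stayed under 5 CPM in all 6 groups. CPM here are scaled by library size alone, without TMM, so levels with THZ1 and DMSO are not compared. The exceptions, named after their values were seen, were as follows, with their highest group. LCP1 reached 985.71 CPM in BxPC3 with THZ1, and was at 210.42 in Panc327 with THZ1. CD68 reached 49.91 in SUIT2 with DMSO. In Panc327 with THZ1, COL1A1 reached 60.41, VWF 15.28 and COL3A1 7.46, and with DMSO PDGFRA reached 9.04. ESAM reached 8.35 in BxPC3 with THZ1.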
